A study of Mus musculus with 12 samples.

How the data were processed

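RNA was measured by bulk sequencing in macrophages sorted from mouse hearts after myocardial infarction. The mice were wild type (WT) or carried 1 copy of a dTomato-Cre insertion at Bhlhe41, here called Bhlhe41Cre. Each genotype was sorted into CCR2low and CCR2hi cells, which gives 4 groups of 3 libraries each. The labels give male C57BL/6N mice and TRIzol extraction of total RNA. The time after infarction, the strand protocol and the number of animals behind each library are not stated in the labels used here.

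Per the submitters' processing notes, reads were called with CASAVA 1.8, aligned with STAR 2.4.0j to mm10 and quantified with RSEM. The RSEM version and the gene annotation are not given in the sources used here. The deposited count table holds expected counts per Ensembl gene as whole numbers (0 values were not whole). Per library, 25 to 43 genes had a count of 0 and a TPM above 0, as rounding of small expected counts gives. The deposited TPM table holds TPM values made by the authors, and each of its columns sums to between 1000000 and 1000001. Columns of the Bhlhe41Cre libraries are named KD in both tables. They were matched to samples by gate and replicate number, and 0 columns were left unmatched. The remaining label fields of these samples are shifted, so the group was taken from the sample title. Which group and number a Bhlhe41Cre column has rests on that match, and its genotype on KD being the only other genotype name in the tables.

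The count table lists 53801 genes, of which 27248 had no count in any library. Total counts per library ran from 17.7 to 20.83 M (1 M is 1e+06 counts), with a median of 19.29 M. A total of 124 symbols are used by more than 1 Ensembl gene, and such genes were kept apart by identifier. Gene positions are those of GENCODE mouse release 21 on GRCm38, the assembly also called mm10, in which 99.82% of the identifiers were found. Neither Cre nor dTomato is a feature of the table, so the inserted sequence could not be counted.

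Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Counts of all 12 libraries were scaled by TMM and filtered with filterByExpr on the groups, which left 14964 genes. A quasi-likelihood model with a mean for each of the 4 groups was fitted with robust dispersion (glmQLFit and glmQLFTest), leaving 8 residual degrees of freedom. The common biological coefficient of variation was 18.9%. The 5 comparisons were CCR2low vs CCR2hi in WT, CCR2low vs CCR2hi in Bhlhe41Cre, Bhlhe41Cre vs WT in CCR2low, Bhlhe41Cre vs WT in CCR2hi, and the CCR2 status by genotype interaction. The last is the CCR2low minus CCR2hi difference in Bhlhe41Cre minus the same difference in WT. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and genes with an adjusted p under 0.05 were called with no fold minimum. The standard error of a log2 fold change is its size over the square root of the F statistic. Group values are mean CPM (counts scaled to 1e+06 per library) on TMM-scaled library sizes with the SD of 3 libraries.

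A gene with no count in a group has no fold change. Its ratio is given as a bound against a floor of 3 counts in each library of that group. With 1 to 3 counts in a group, the ratio has a 95% counting interval. These floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

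The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap, the 8 largest changes per direction. For the interaction it took 5 per direction and dropped the overlap condition. Ccr2, Bhlhe41 and Bhlhe40 were always included, and up to 4 genes per list were taken by p. The 27 lists cover macrophage programs (resident cardiac macrophage, lipid-associated macrophage, monocyte, inflammatory cytokines and chemokines, alternative activation, type I interferon response, MHC class II antigen presentation, efferocytosis and lipid efflux, matrix remodelling, growth factors), metabolism and stress (glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, cell cycle, circadian clock, immediate early and dissociation stress) and cell type markers (macrophage identity, dendritic cell, neutrophil, T and NK cell, B cell, mast cell, erythroid, fibroblast, endothelial, mural, cardiomyocyte). Each was tested in each comparison with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and p values were adjusted over the 135 tests. The adjusted p with a correlation estimated from the data is given beside it. Within each list the number of called genes was also counted with p values adjusted over the list alone.

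Whether equal replicate numbers mark libraries of the same animal was checked by correlating residuals. Between the gates of Bhlhe41Cre the correlations were 0.23, 0.12 and 0.40, all above the limit of 0.1 set for a pairing. However, CCR2low replicate 2 correlated more, at 0.22, with a CCR2hi library of another number. Only replicates 1 and 3 matched their own number best. Between the gates of WT they were -0.06, 0.03 and -0.05. The comparisons were unpaired, and a fit with replicate blocks was 1 of the alternatives. On simulated counts with no other group difference, 67, 67 and 66 of the 14964 genes were changed by 1.5, 2 and 4 times. The test for CCR2low vs CCR2hi in WT found 17.9%, 65.7% and 92.4% of these, with 6 false calls. For the interaction these shares were 4.48%, 34.3% and 83.3%, with 3 false calls. Far fewer genes were changed there than were called in the data. The simulation therefore does not measure false calls where the cell content of the groups differs. With a GC trend added to unchanged genes, 4255 were falsely called without a GC correction and 7 with it.

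Some alternatives changed more than 1 choice. DESeq2 changed the test and the scaling, limma-trend on TPM the test, the unit, the scaling and the filter, and fits to fewer libraries also the genes tested and the scaling factors. They were DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) with TPM of at least 1 in at least 3 libraries, RLE factors, library size only, no low-count filter, a filter of at least 5 CPM in at least 3 libraries, no robust dispersion, glmTreat against a 1.5-fold change, each library left out, a fit to the 6 libraries compared, and replicate blocks. After the data were seen, 4 were added: a GC and length correction from smooth curves with a span of 0.3 on the longest annotated transcript, scaling of each library to the geometric mean of its macrophage identity genes, leaving out WT CCR2low replicate 3 and WT CCR2hi replicate 2 together, and autosomal genes only. Each comparison was also repeated on other splits of the same libraries. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

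The p values measure only the spread between these libraries, which may be technical where libraries of a group come from the same animals. Reads were not used here.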

Results

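Gene expression was measured by bulk RNA sequencing in macrophages sorted from mouse hearts after ligation of a coronary artery. The libraries form 4 groups of 3: WT CCR2low, WT CCR2hi, Bhlhe41Cre CCR2low and Bhlhe41Cre CCR2hi. CCR2 is the receptor for the monocyte chemoattractant CCL2, and its level on the cell surface was the basis of the sort. Total counts ran from 19.77 to 20.83 M in WT CCR2low, from 18.64 to 19.79 M in WT CCR2hi, from 18.78 to 19.31 M in Bhlhe41Cre CCR2low and from 17.7 to 19.45 M in Bhlhe41Cre CCR2hi, where 1 M is 1e+06 counts. All group values are mean CPM ± SD, n = 3, positions are on GRCm38 (mm10), and all changes are log2 fold changes ± SE with edgeR adjusted p values unless stated. They measure the spread between these libraries, whose numbers are not stated to be animals.

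Bhlhe41 (6:145858243-145865558), a basic helix-loop-helix transcriptional repressor and the locus of the Cre insertion, was at 35.9 ± 4.70 CPM in WT CCR2low and 37.4 ± 9.37 CPM in WT CCR2hi. In the Bhlhe41Cre libraries it was at 21.1 ± 6.83 CPM in CCR2low and 7.98 ± 1.35 CPM in CCR2hi. The counts behind these means were 774, 642 and 671, then 920, 756 and 531, then 447, 477 and 226, then 160, 198 and 132. Within CCR2hi, Bhlhe41 was lower in Bhlhe41Cre (-2.23 ± 0.257, adjusted p = 5.14e-05). Within CCR2low its change was -0.77 ± 0.244 (adjusted p = 0.0221), a call that 11 of 25 alternatives ended, with adjusted p from 0.00366 to 0.289. Relative to the macrophage identity genes it was -0.53 (adjusted p = 0.414). Without Bhlhe41Cre CCR2low replicate 3 this change was -0.36 (adjusted p = 0.183). Its call also ended without WT CCR2low replicate 1 (0.0792), WT CCR2hi replicate 1 (0.0678) and Bhlhe41Cre CCR2hi replicate 1 (0.0961), 2 (0.089) or 3 (0.0855). In the CCR2low vs CCR2hi in Bhlhe41Cre comparison Bhlhe41 was higher in CCR2low (1.40 ± 0.255, adjusted p = 0.000383), which turned to -0.54 (adjusted p = 0.224) relative to the macrophage identity genes. In WT the gates differed by -0.06 ± 0.24 (adjusted p = 0.847), against -3.34 (adjusted p = 1.58e-06) relative to the macrophage identity genes, a scale that moved the median gene by -3.12. On that scale Bhlhe41 was -3.33 (adjusted p = 0.000125) between genotypes within CCR2hi. The interaction was 1.46 ± 0.349 (adjusted p = 0.0186), with a range of 0.000984 to 0.104 over alternatives, and 2.8 (adjusted p = 0.00966) on that scale. This call ended without WT CCR2low replicate 2 (0.0528) and without Bhlhe41Cre CCR2low replicate 1 (0.0539).

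Bhlhe40 (6:108660629-108666925), the close paralog of Bhlhe41, was at 420.6 ± 25.1 CPM in WT CCR2low, 685.2 ± 175.7 in WT CCR2hi, 445.8 ± 26.7 in Bhlhe41Cre CCR2low and 430.2 ± 37.0 in Bhlhe41Cre CCR2hi. It was lower in CCR2low than CCR2hi in WT (-0.70 ± 0.161, adjusted p = 0.00195) and lower in Bhlhe41Cre than WT within CCR2hi (-0.67 ± 0.161, adjusted p = 0.00665). Against a 1.5-fold minimum both of these calls ended. Its change between genotypes in CCR2low was 0.08 ± 0.16 (adjusted p = 0.698). Relative to the macrophage identity genes these 3 values were -4.01 (adjusted p = 9.19e-08), -1.81 (adjusted p = 0.00105) and 0.29 (adjusted p = 0.624). Ccr2 (9:124101950-124113557) was at 31.5 ± 12 CPM in WT CCR2low, 65.6 ± 22.4 in WT CCR2hi, 76.8 ± 18.3 in Bhlhe41Cre CCR2low and 77.3 ± 10.5 in Bhlhe41Cre CCR2hi. Ccr2 was lower in CCR2low than CCR2hi in WT (-1.06 ± 0.301, adjusted p = 0.00825), with adjusted p from 0.000555 to 0.434 over alternatives, the highest after the GC and length correction. In Bhlhe41Cre the gates differed by -0.01 ± 0.296 (adjusted p = 0.983). Between genotypes Ccr2 was higher in Bhlhe41Cre within CCR2low (1.28 ± 0.303, adjusted p = 0.00439), a call that ended after the GC and length correction (0.46, adjusted p = 0.393, range 7.94e-05 to 0.393). Relative to the mean of the macrophage identity genes, Ccr2 stood at 2.72 ± 0.943% in WT CCR2low, 47.9 ± 3.24% in WT CCR2hi, 7.60 ± 0.882% in Bhlhe41Cre CCR2low and 29.99 ± 1.38% in Bhlhe41Cre CCR2hi. On that scale it was lower in CCR2low in both genotypes, by -4.14 (adjusted p = 1.03e-08) in WT and -1.98 (adjusted p = 1e-05) in Bhlhe41Cre, where that scale moved the median gene by -3.12 and -1.96. Between genotypes it was 1.48 (adjusted p = 0.00369) within CCR2low and -0.67 (adjusted p = 0.0414) within CCR2hi on that scale.

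**Figure D1:**
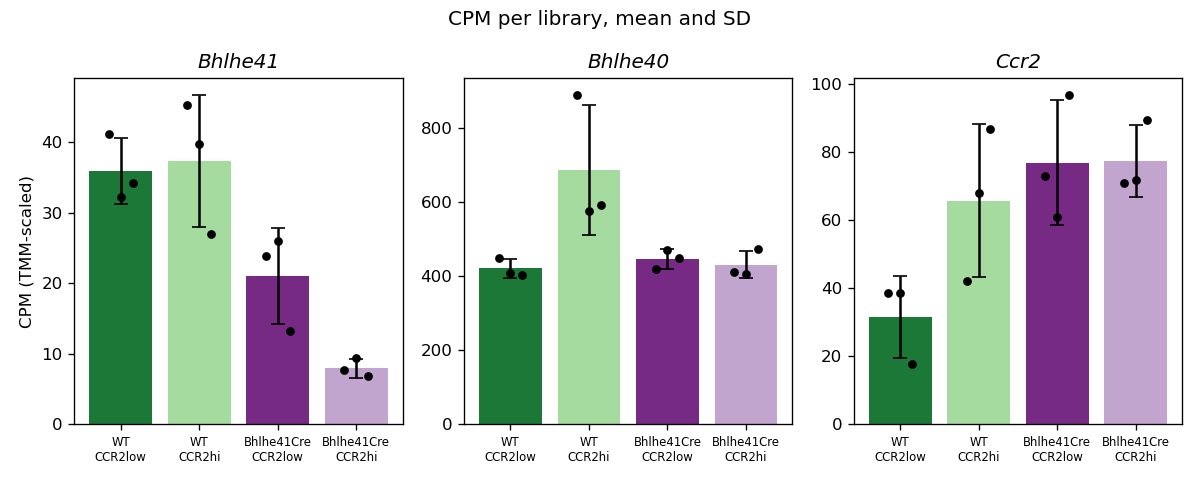
CPM of Bhlhe41, Bhlhe40 and Ccr2 in each library (points), with the group mean (bar) and SD (line), n = 3. Bhlhe41 is at 7.98 ± 1.35 CPM in Bhlhe41Cre CCR2hi against 37.4 ± 9.37 CPM in WT CCR2hi, while Ccr2 is at 76.8 ± 18.3 and 77.3 ± 10.5 CPM in the CCR2low and CCR2hi libraries of Bhlhe41Cre.

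The gates differed in the cells whose genes they held. Genes of the fibroblast list took 10.2 ± 0.485% of counts in WT CCR2hi and 5.68 ± 0.698% in Bhlhe41Cre CCR2hi, against 0.960 ± 0.246% in WT CCR2low and 0.429 ± 0.221% in Bhlhe41Cre CCR2low. Genes of the macrophage identity list took 3.46 ± 0.152% in WT CCR2low and 3.17 ± 0.171% in Bhlhe41Cre CCR2low, against 0.415 ± 0.161% in WT CCR2hi and 0.928 ± 0.130% in Bhlhe41Cre CCR2hi. Scaling to the macrophage identity genes therefore moved the median gene by -3.12 in CCR2low vs CCR2hi in WT, -1.96 in CCR2low vs CCR2hi in Bhlhe41Cre, 0.20 in Bhlhe41Cre vs WT in CCR2low, -0.96 in Bhlhe41Cre vs WT in CCR2hi and 1.17 in the interaction. Library size scaling moved it by -0.10, -0.21, -0.02, 0.09 and -0.11. Where the median of a called list turns under the macrophage scaling this is stated with it. Such turns follow from the move of all genes, and camera, which tests a list against the other genes, kept 54 of the 60 list calls under that scaling, with 0 opposite. Ranges given over alternatives leave this scaling out. Of the single called genes, that scaling called 3766, 2661, 0, 35 and 0 in the opposite direction, in the same order. Xist, transcribed from the inactive X chromosome of females, had 2027 to 3699 counts in Bhlhe41Cre CCR2low and 1403 to 1798 in Bhlhe41Cre CCR2hi, against 0 in WT CCR2low and 3, 0 and 0 in WT CCR2hi. The 4 Y-linked genes had 668 to 897 counts in WT CCR2low and 1056 to 1741 in WT CCR2hi. In Bhlhe41Cre they had 1162, 1446 and 105 counts in CCR2low and 709, 1413 and 182 in CCR2hi. The labels call all mice male.

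**Figure D2:**
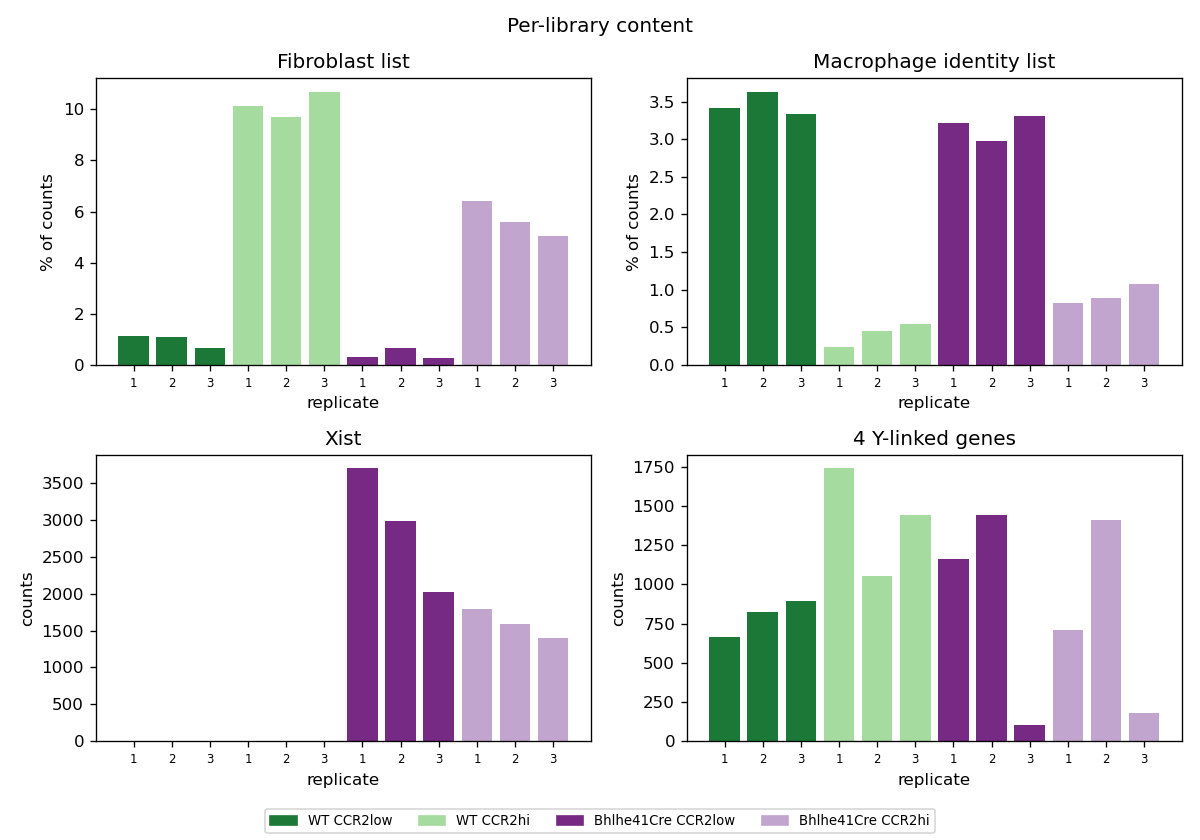
Percent of counts in the fibroblast and macrophage identity lists, and counts of Xist and of 4 Y-linked genes, in each of the 12 libraries (bars). The fibroblast list holds 10.2 ± 0.485% of counts in WT CCR2hi and 0.960 ± 0.246% in WT CCR2low, and Xist is at 1403 to 3699 counts in every Bhlhe41Cre library.

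Within groups, libraries correlated at r = 0.973 to 0.988 over 12 pairs, and between groups at 0.797 to 0.954, across genes, which are not independent replicates. On the first principal component, with 64.0% of the variance, the CCR2low libraries lay at 54.21 or above and the CCR2hi libraries at -43.6 or below. On the second, with 16.9%, WT CCR2low lay at 55.67 to 59.69 and Bhlhe41Cre CCR2low at -46.53 to -20.7.

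**Figure D3:**
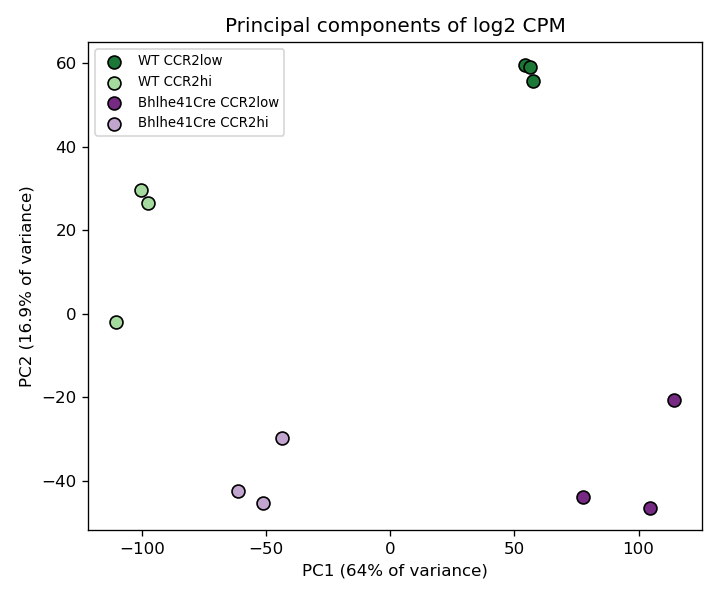
First and second principal components of the log2 CPM of the 12 libraries (points, by group), with 64.0% and 16.9% of the variance. The first parts the gates, with all CCR2low libraries at 54.21 or above, and the second parts the CCR2low libraries by genotype.

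CCR2low vs CCR2hi in WT asks how the 2 sorted populations of an infarcted WT heart differ. CCR2low libraries held far more RNA of macrophage genes. Gpnmb, a glycoprotein of lipid-laden macrophages, was at 4624 ± 847 CPM in CCR2low and 40.8 ± 14.2 in CCR2hi (6.82 ± 0.389, adjusted p = 4.03e-08). Fcna, a ficolin of resident macrophages, was at 230 ± 64.6 and 2.11 ± 0.977 CPM (6.77 ± 0.322, adjusted p = 1.75e-08). CCR2hi libraries held more RNA of fibroblast marker genes. Among them Postn (3:54361109-54391037), a matrix protein of activated fibroblasts, was at 149 ± 33.2 CPM in CCR2low and 5250 ± 2007 in CCR2hi (-5.14 ± 0.588, adjusted p = 6.89e-06).

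Among the largest increases in CCR2low was Marco (1:120474538-120505024), a scavenger receptor, at 248 ± 184 against 0.208 ± 0.188 CPM (10.20 ± 0.81, adjusted p = 4.72e-07). Alox15 (11:70344152-70352031), a lipoxygenase of peritoneal macrophages, was at 79.9 ± 79.8 against 0.204 ± 0.0885 CPM (8.57 ± 0.821, adjusted p = 1.66e-06). Kap (6:133849851-133853762), an androgen-regulated gene of the kidney tubule, was at 24.2 ± 2.98 CPM in CCR2low with no count in CCR2hi, at least 158-fold higher (adjusted p = 5.37e-07). Pck1 (2:173153048-173159273), an enzyme of gluconeogenesis, was higher with a counting interval of 161 to 35500 for the ratio (adjusted p = 2.16e-05). Among the named genes, 4 of fat cells were higher too, and most of their counts lay in WT CCR2low replicate 3. They were Cfd (10:79890853-79892655; 8.42 ± 1.57, adjusted p = 0.000772), Cyp2e1 (7:140763739-140774987; 8.26 ± 1.61, adjusted p = 0.00106), Adipoq (16:23146536-23158028; 7.65 ± 1.42, adjusted p = 0.000586) and Cidec (6:113424634-113435760; ratio interval 183 to 2590, adjusted p = 0.000702). Cidec lost its call under limma-voom (0.0575, range 1.14e-06 to 0.0575). Without WT CCR2low replicate 3 the values were 4.97 for Cfd, 5.05 for Cyp2e1, 5.03 for Adipoq, 9.46 for Marco and 7.35 for Alox15. Cidec and Pck1, with few counts in CCR2hi, went from 8.88 to 5.98 and from 9.33 to 8.08 there. Cidec was at 8.16 and 9.72 without WT CCR2hi replicates 1 and 3, and Pck1 at 8.7 and 11.2 without replicates 1 and 2. Marco was at 9.42 and 10.88 without WT CCR2hi replicates 1 and 2, Cfd at 7.82 without replicate 1 and Adipoq at 9.13 without replicate 3. Among the largest decreases were Dio2 (12:90724552-90738438), a thyroid hormone deiodinase, at 0.974 ± 0.267 against 37.7 ± 13.2 CPM (-5.26 ± 0.331, adjusted p = 7.17e-08), and Hmcn2 (2:31314415-31460738), a basement membrane protein, at 3.84 ± 0.415 against 112 ± 15.7 CPM (-4.87 ± 0.271, adjusted p = 3.48e-08). Thbs4 (13:92751590-92794818), a matrix thrombospondin, was at -4.82 and Col8a1 (16:57624258-57754737), a short-chain collagen, at -4.52. Kcnk2, Angptl1 and C1qtnf3 completed this group at -4.76, -4.67 and -4.66.

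All 17 macrophage identity genes were higher in CCR2low, 17 also when adjusted over the list alone, among them Ctss (3.71), Itgam (3.10) and Cd14 (2.75). Under macrophage scaling, which centres these genes, 2 were called higher and 1 lower, with Itgam at 0.02 and Cd14 at -0.42 (adjusted p = 0.143). On the main scale the camera adjusted p was 2.54e-15 and the adjusted p = 0.162 with an estimated correlation. Of 22 lipid-associated macrophage genes, 20 were higher and 2 lower, the same adjusted over the list alone, led by Gpnmb and by Spp1, which encodes osteopontin (4.81 ± 0.266; 2949 ± 253 against 105 ± 7.82 CPM), while macrophage scaling gave 8 higher and 8 lower with a median of 0.14. Camera gave 2.54e-15, and adjusted p = 0.0884 with an estimated correlation. Of 23 resident cardiac macrophage genes, 20 were higher, 1 lower and 2 not called (21 and 1 adjusted over the list alone), with Fcna, Timd4 (6.24, with 5.52 and 7.15 without WT CCR2hi replicates 1 and 3) and Lyve1 (5.32) among them, while macrophage scaling gave 10 higher and 7 lower with a median of 0.56. Camera gave 8.94e-12, and adjusted p = 0.0884 with an estimated correlation. Of 24 inflammatory cytokine and chemokine genes, 18 were higher and 2 lower, the same adjusted over the list alone, with Tnf (3.29), Il1a (3.05) and Cxcl2 (2.20) higher, and the list median turned from 2.14 to -1.04 under macrophage scaling. Camera gave 1.44e-06, and adjusted p = 0.198 with an estimated correlation. Efferocytosis and lipid efflux, with Msr1 (3.68) and Mertk (2.76), had 16 of 27 higher and 6 lower, the same adjusted over the list alone, with a median of 1.28 that turned to -1.89 under macrophage scaling. Camera gave 0.00105, and adjusted p = 0.0761 with an estimated correlation. Alternative activation, with Arg1 (4.54) and Il10 (3.22), had 12 of 21 higher and 4 lower, the same adjusted over the list alone, with a median of 1.26 that turned to -1.95. Camera gave 0.00952, and adjusted p = 0.143 with an estimated correlation.

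Of the metabolic lists, oxidative phosphorylation and glycolysis and hypoxia were called higher in CCR2low on the main scale. Of 41 oxidative phosphorylation genes, 32 were higher and none lower (34 adjusted over the list alone), with Cox5a (1.11) and Sdhd (0.98), and the median turned from 0.60 to -2.60 under macrophage scaling. Camera gave 0.000804, and adjusted p = 0.77 with an estimated correlation, with 0.177 after the GC and length correction (range over alternatives 0.000571 to 0.77). Of 27 glycolysis and hypoxia genes, 19 were higher and 3 lower (20 and 3 adjusted over the list alone), with Pfkfb4 (1.94) and Pgam1 (1.43), and the median turned from 0.73 to -2.53. Camera gave 0.00737, and adjusted p = 0.198 with an estimated correlation. Marker lists of structural cells were lower in CCR2low. All 16 fibroblast genes were lower, 16 also adjusted over the list alone, with Lum (-4.06), Col5a1 (-3.34) and Mgp (-2.80) (camera 1.34e-11; adjusted p = 0.288 with an estimated correlation). Of 13 endothelial genes, 12 were lower by either count, over all genes tested or adjusted over the list alone, with Kdr (-2.12) and Cldn5 (-1.62) (camera 0.00037; adjusted p = 0.571 with an estimated correlation). Of 10 mural genes, 9 were lower by either count, with Pdgfrb (-2.65) and Tagln (-1.89) (camera 0.00105; adjusted p = 0.3 with an estimated correlation).

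The other 16 lists were not called in WT, and their counts follow as higher and lower genes of those tested with the camera adjusted p. Monocyte had 9 and 3 of 18 (0.0646), neutrophil 3 and 0 of 13 (0.156), T and NK cell 6 and 1 of 15 (0.278), B cell 2 and 1 of 9 (0.705), mast cell 0 and 2 of 6 (0.707), dendritic cell 4 and 7 of 16 (0.643) and cardiomyocyte 1 and 3 of 19 (0.51). Erythroid had 0 and 0 of 5 (0.834), cell cycle 10 and 6 of 33 (0.613), cholesterol synthesis 6 and 4 of 22 (0.731), growth factors 13 and 8 of 26 (0.36), immediate early and dissociation stress 6 and 8 of 24 (0.654), matrix remodelling 11 and 11 of 24 (0.705), and type I interferon response 11 and 4 of 27 (0.36). Under macrophage scaling, which called 14199 of 14964 genes lower, 16 monocyte, 15 dendritic cell, 33 cell cycle, 26 type I interferon and 9 neutrophil genes were lower and none of these lists' genes higher, and the monocyte median turned from 1.08 to -2.03. For circadian clock, with 6 and 6 of 19 (0.643), and MHC class II antigen presentation, with 2 and 1 of 14 (0.903), the sign of the list median differed from that of the test.

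In all, 8949 of 14964 genes (59.8%) differed between the gates in WT, 4454 higher and 4495 lower, of which 5406 changed by more than 2-fold. The share higher was 49.8% on the main scale, 32.0% with limma-trend on TPM, which also filters differently (2538 higher and 5382 lower) and 0.824% after macrophage scaling (118 higher and 14199 lower). Left-out libraries moved it as far as 37.7%, reached without Bhlhe41Cre CCR2hi replicate 1 or 3, which are not in this comparison. Another TMM reference library moved the log2 fold changes by -0.2 to 0.05.

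CCR2low vs CCR2hi in Bhlhe41Cre asks the same of the Bhlhe41Cre hearts. All 17 macrophage identity genes were higher in CCR2low on the main scale, and all 16 fibroblast marker genes were lower. Gpnmb (6:49036546-49070929) was at 3469 ± 301 against 253 ± 102 CPM (3.78 ± 0.336, adjusted p = 8.63e-07), and Spp1 at 9949 ± 1323 against 987 ± 353 CPM (3.33 ± 0.248, adjusted p = 2.53e-07). Marco was at 35.7 ± 11.9 against 0.913 ± 0.453 CPM (5.28 ± 0.645, adjusted p = 1.96e-05). Cthrc1 (15:39076932-39087121), a secreted protein of activated fibroblasts, was at 15.7 ± 10.5 against 283 ± 61.5 CPM (-4.17 ± 0.413, adjusted p = 2.08e-06, and -4.86 without Bhlhe41Cre CCR2low replicate 2).

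Other large increases in CCR2low were Vsig4 (X:96247203-96293438), a complement receptor of resident macrophages, at 9.81 ± 1.98 against 0.274 ± 0.304 CPM (5.11 ± 0.627, adjusted p = 1.34e-05), and Alox15 at 12.4 ± 2.43 against 0.618 ± 0.167 CPM (4.30 ± 0.698, adjusted p = 0.000184). Cd5l (3:87357881-87371073), a secreted scavenger receptor, was at 115 ± 41.2 against 8.89 ± 3.98 CPM (3.70 ± 0.427, adjusted p = 7.99e-06), and Htr2b (1:86099026-86111970), a serotonin receptor, was 4.11 ± 0.231 higher (adjusted p = 8.07e-08). Stra6l (4:45848664-45887008) and Rnf128 were 3.82 and 3.78 higher. Pi16 (17:29317680-29330593), a marker of adventitial fibroblasts, was at 23.5 ± 8.15 against 424 ± 114 CPM (-4.18 ± 0.259, adjusted p = 1.02e-07). Cyp1a1 (9:57687928-57703824), a target of the aryl hydrocarbon receptor, was at -4.37, Ebf2 (14:67233292-67430918), a mesenchymal transcription factor, at -4.26 and Cilp (9:65265180-65280605), a cartilage and scar matrix protein, at -4.16. Nkd2, Col9a2 and Clec11a followed at -4.24, -4.18 and -4.16. Without Bhlhe41Cre CCR2low replicate 2, Ebf2, Col9a2, Cilp and Clec11a were at -5.63, -5.34, -4.85 and -4.75. Vsig4 was at 6.54 without Bhlhe41Cre CCR2hi replicate 2 and Cyp1a1 at -3.6 without replicate 1.

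All 17 macrophage identity genes were higher by either count, with Cd68 (2.54) and Ctss (2.22), and camera gave 9.9e-10. The adjusted p = 0.3 with an estimated correlation, and under macrophage scaling, which centres these genes, the list median went from 1.8 to -0.14. Of 22 lipid-associated macrophage genes, 18 were higher and 1 lower by either count, with Ctsl (2.35) and Lipa (2.23) (camera 2.78e-12; adjusted p = 0.138 with an estimated correlation), and 9 higher and 6 lower under macrophage scaling. Of 23 resident cardiac macrophage genes, 21 were higher and 1 lower by either count, with Fcna (3.48), Mrc1 (2.89) and Selenop (2.10) (camera 9.9e-10; adjusted p = 0.188 with an estimated correlation), and 9 higher and 6 lower under macrophage scaling. Efferocytosis and lipid efflux had 16 of 27 higher and 6 lower by either count, with Mertk (2.37), Abca1 (2.23) and Tyro3 (-3.31), and its median of 1.10 turned to -0.84 under macrophage scaling (camera 0.00442; adjusted p = 0.143 with an estimated correlation). Inflammatory genes had 14 of 24 higher and 5 lower by either count, with Ccl8 (2.73), Tnf (1.55) and Cxcl9 (-2.14), and a median of 0.81 that turned to -1.12. Camera gave 0.0291 with adjusted p = 0.59 with an estimated correlation, and 0.141 after the GC and length correction (range 0.015 to 0.59).

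Structural cell markers were lower in Bhlhe41Cre CCR2low without exception, by either count. They were 16 of 16 fibroblast genes (Lum -3.83, Tcf21 -3.79; camera 5.7e-14; adjusted p = 0.198 with an estimated correlation), 10 of 10 mural genes (Tagln -3.57, Pdgfrb -3.43; camera 3.14e-11; adjusted p = 0.0573 with an estimated correlation), 19 of 19 cardiomyocyte genes (Mb -2.85, Tnnt2 -2.20; camera 5.1e-08; adjusted p = 0.235 with an estimated correlation) and 13 of 13 endothelial genes (Ly6c1 -2.97, Cldn5 -2.35; camera 5.84e-08; adjusted p = 0.3 with an estimated correlation). Neutrophil genes S100a9 (-2.95), Cxcr2 (-2.90) and S100a8 (-2.62) were lower, with 9 of 13 list genes lower and 1 higher, and the list was not called (0.162). The remaining 17 lists were not called either, with camera adjusted p from 0.0605 to 0.809. The cell cycle and growth factor lists had medians of the opposite sign to the test.

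In this comparison 8094 genes (54.1%) differed, 3733 higher and 4361 lower, of which 4890 changed by more than 2-fold. The share higher was 46.1% on the main scale, 31.5% with limma-trend on TPM (2148 and 4664), 32.0% with library size only (2533 and 5384), 57.3% with a filter of 5 CPM and 0.603% after macrophage scaling (82 and 13522). Across genes, which are not independent replicates, the gate differences of the 2 genotypes correlated at r = 0.756 (rho = 0.75). Both fits called 2869 genes higher, where independent calls give 1111, and 3272 lower, where they give 1310, and 166 were called in opposite directions.

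**Figure D4:**
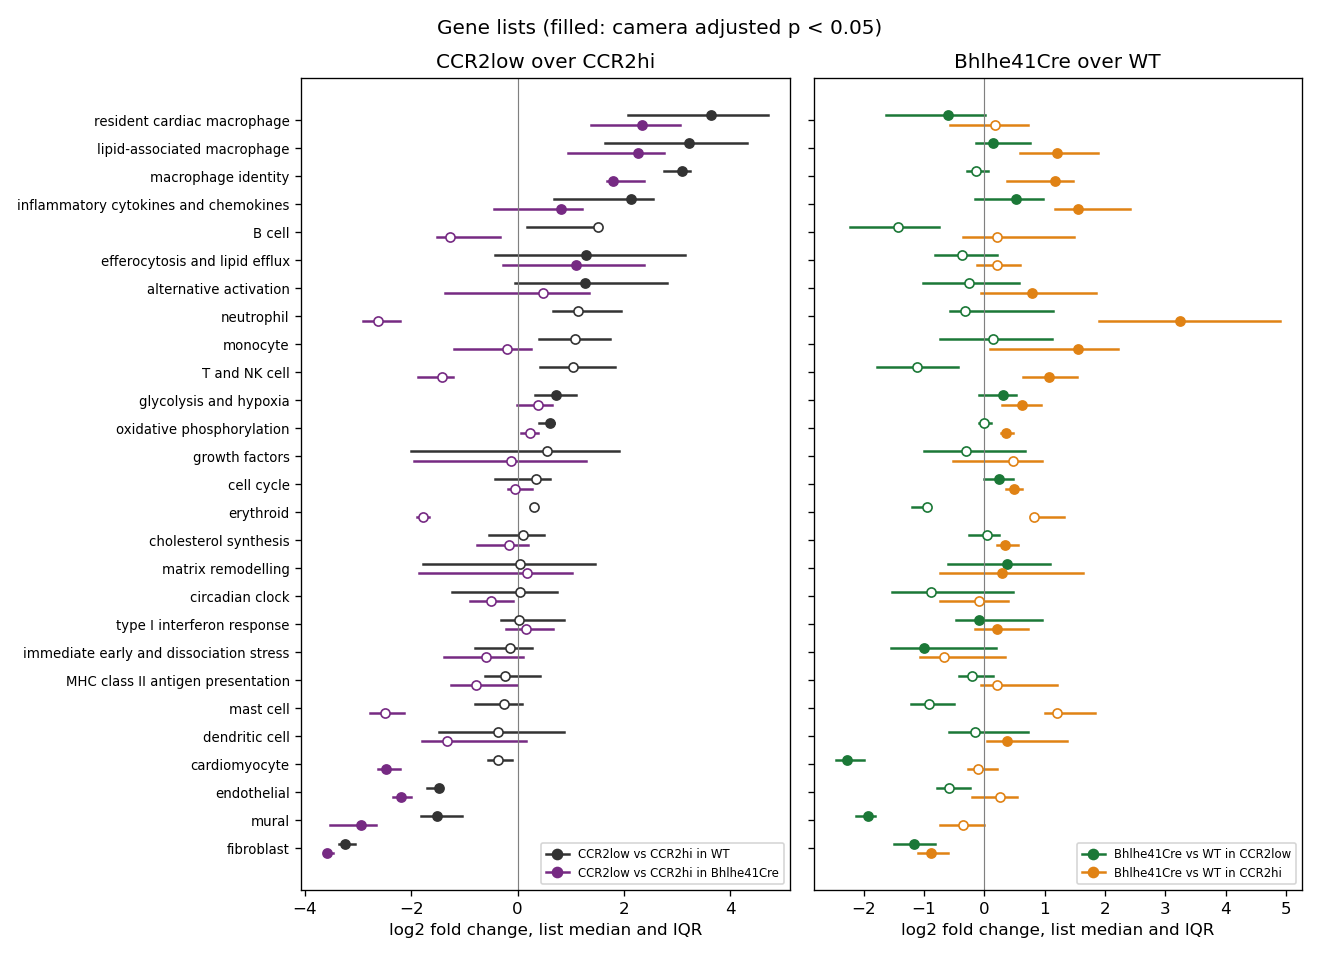
Median log2 fold change (points) and interquartile range (lines) of each gene list for the gate and genotype comparisons, filled where the camera adjusted p is under 0.05. The fibroblast list lies at -3.25 and -3.59 for CCR2low over CCR2hi, while medians such as 2.14 for inflammatory genes in WT turn to -1.04 under macrophage scaling, as do the other lists named so in the text.

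Bhlhe41Cre vs WT in CCR2low asks what differs in the CCR2low cells of hearts with the insertion. Of 24 inflammatory genes 9 were higher in Bhlhe41Cre and 1 lower, of 23 resident cardiac macrophage genes 10 were lower and 3 higher, and of 24 immediate early genes 15 were lower and 3 higher. None of the 3 list calls held with an estimated correlation. How far fat, kidney or mesothelial tissue in WT CCR2low gave the fall in resident genes was not tested. Cxcl3 (5:90786103-90789600), a neutrophil chemoattractant, was at 422 ± 43.2 CPM in Bhlhe41Cre and 24.6 ± 6.52 in WT (4.10 ± 0.274, adjusted p = 2.29e-06). Ifnb1 (4:88522025-88522774), interferon beta, was at 22.9 ± 3.18 against 0.789 ± 0.0710 CPM (4.85 ± 0.316, adjusted p = 1.95e-06). Hmox1, the heme-degrading enzyme, was at 4553 ± 213 against 1019 ± 153 CPM (2.16 ± 0.277, adjusted p = 0.000115). Fcna was at 26 ± 1.12 against 230 ± 64.6 CPM (-3.14 ± 0.26, adjusted p = 9.68e-06).

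Xist (X:103460366-103483254) was at 160 ± 39.5 CPM in Bhlhe41Cre with no count in WT, at least 1040-fold higher (adjusted p = 1.73e-07). Slc7a11 (3:49892526-50443614), the cystine transporter, was at 176 ± 65.5 against 6.31 ± 0.809 CPM (4.80 ± 0.576, adjusted p = 0.000106). Inhba (13:16011851-16031621), a subunit of activin, and Nrg1 (8:31814551-32884029), an ErbB ligand, were each 3.46 higher (adjusted p = 8.43e-05 and 3.12e-05), as was B3gnt5. Tpm3-rs7 (14:113314608-113316754), a copy of a tropomyosin gene that shares sequence with its parent, was at 113 ± 31.7 against 2.58 ± 1.12 CPM, and its change of 5.45 is uncertain for that reason. The largest decreases were the kidney and fat cell genes that stood out in WT CCR2low. Kap was at least 145-fold lower (adjusted p = 1.47e-05), and Pck1 had a ratio interval of 113 to 3400. The value of Pck1 was -8.44, and -7.19 without WT CCR2low replicate 3. Car3 (3:14863512-14872523), a carbonic anhydrase of fat and muscle, was at 0.566 ± 0.301 against 104 ± 122 CPM (-7.49 ± 0.995, adjusted p = 0.000193). Plin1 (7:79720218-79732903), a lipid droplet protein, was at -6.49, Cfd at -8.92, Cidec at -7.14, Adipoq at -6.73 and Cyp2e1 at -6.58. The calls of Cfd, Cidec, Adipoq and Cyp2e1 ended under limma-voom alone of the alternatives, with adjusted p of 0.0561, 0.0743, 0.0578 and 0.0583, where the lowest were 5.55e-05, 0.000107, 6.19e-06 and 3.52e-07. Without WT CCR2low replicate 3, which held most of their counts, Cfd was at -5.47, Cidec at -4.24, Adipoq at -4.1, Cyp2e1 at -3.37, Car3 at -5.89 and Plin1 at -5.4. Without Bhlhe41Cre CCR2low replicate 1, Cfd, Cidec and Adipoq were at -9.7, -8.74 and -7.75, and without replicate 3 Plin1 was at -5.83.

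The medians of the following lists kept their sign under macrophage scaling except where stated. It called fewer of their genes, with 5 cell cycle and 5 glycolysis and hypoxia genes higher, 11 immediate early genes lower and 2 higher, and 8 resident genes lower and 2 higher. Of 24 inflammatory genes, 9 were higher and 1 lower by either count, with Ccl5 (2.29), Il1rn (1.82) and Cxcl2 (1.31 ± 0.165; 4396 ± 451 against 1772 ± 135 CPM) (camera 8.37e-05; adjusted p = 0.289 with an estimated correlation). Among 24 immediate early and dissociation stress genes, 15 were lower and 3 higher (15 and 4 adjusted over the list alone), with Btg2 (-2.91), Fosb (-1.88) and Jund (-1.54) lower and Hsp90aa1 (2.71) higher (camera 0.000283; adjusted p = 0.355 with an estimated correlation). Of the 33 cell cycle genes 9 were higher by either count, with Mki67 (2.08), Bub1 (1.56) and Nusap1 (1.28), and 24 were not called (camera 0.00129; adjusted p = 0.729 with an estimated correlation). Lipid-associated genes, with Spp1 (1.75), had 8 of 22 higher and 2 lower by either count (camera 0.0102; adjusted p = 0.57 with an estimated correlation). Glycolysis and hypoxia, with Slc2a1 (1.13) and Ero1l (1.04), had 10 of 27 higher and 4 lower by either count (camera 0.0159; adjusted p = 0.235 with an estimated correlation). Resident cardiac macrophage genes, with Lyve1 (-2.95), Timd4 (-2.85) and Ltc4s (-2.26), had 10 of 23 lower and 3 higher by either count (camera 0.0162; adjusted p = 0.643 with an estimated correlation). Matrix remodelling, with Mmp13 (2.17) and Mmp19 (1.78) higher and Mmp2 (-2.12) lower, had 10 of 24 higher and 4 lower (10 and 5 adjusted over the list alone; camera 0.0386; adjusted p = 0.359 with an estimated correlation). Type I interferon response, with Oasl1 (3.09), Ifit1 (2.24) and Rsad2 (1.91), had 8 of 27 higher and 3 lower (8 and 4 adjusted over the list alone; camera 0.0431; adjusted p = 0.782 with an estimated correlation). That test was toward higher values while the list median was -0.08, and the median turned to 0.14 under macrophage scaling.

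Among markers of other heart cells, the cardiomyocyte, mural and fibroblast lists were called lower in Bhlhe41Cre CCR2low, while the endothelial list was not called, with 4 of 13 genes lower (0.148). Lower were 18 of 19 cardiomyocyte genes, 19 adjusted over the list alone, with Ckmt2 (-3.10), Myh6 (-2.41) and Mb (-2.40) (camera 1.51e-12; adjusted p = 0.143 with an estimated correlation), and 10 of 10 mural genes by either count, with Kcnj8 (-2.36) and Notch3 (-2.18) (camera 1.82e-11; adjusted p = 0.0573 with an estimated correlation). Fibroblast genes, with Fbln1 (-1.73) and Col1a1 (-1.61), had 12 of 16 lower, 13 adjusted over the list alone (camera 0.000367; adjusted p = 0.618 with an estimated correlation), and 3 lower under macrophage scaling. Of 17 macrophage identity genes 1 was lower and 16 were not called, and that list had an adjusted p of 0.913. The other lists not called had camera adjusted p from 0.132 to 0.916. Medians of the alternative activation, dendritic cell, MHC class II and neutrophil lists had the opposite sign to the test.

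Between genotypes 6441 genes (43%) differed in CCR2low, 2448 higher and 3993 lower, of which 3043 changed by more than 2-fold. The share higher was 38.0% on the main scale, 52.4% with no filter, 50.8% with a filter of 5 CPM, 53.3% in a fit of the 6 libraries compared, 53.9% after macrophage scaling (1298 and 1109) and up to 56.8% with a library left out. That highest share was reached without Bhlhe41Cre CCR2hi replicate 1, which is not in this comparison. Another TMM reference library moved the log2 fold changes by -0.03 to 0.19. Fold changes correlated with GC content across genes at rho = -0.46, with a median of 0.62 for the 1381 genes under 42% GC and -0.42 for the 3264 over 54%. After the GC and length correction 4733 of the calls kept their direction and 35 were opposite.

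Bhlhe41Cre vs WT in CCR2hi asks the same of the CCR2hi cells. The inflammatory, monocyte and neutrophil lists were called higher in Bhlhe41Cre with the preset correlation and not with an estimated correlation (adjusted p = 0.0573, 0.0573 and 0.198). S100a8 (3:90668978-90670035) and S100a9 (3:90692632-90695721), the calprotectin subunits abundant in neutrophils, were at 354 ± 92.2 against 11.8 ± 9.69 CPM (4.90 ± 0.586, adjusted p = 9.36e-05) and 434 ± 75.6 against 14.8 ± 11.7 CPM (4.87 ± 0.558, adjusted p = 6.66e-05), with 5.8 and 5.73 without WT CCR2hi replicate 1. Cxcl2, a neutrophil chemoattractant, was at 2670 ± 217 against 386 ± 79.7 CPM (2.79 ± 0.174, adjusted p = 5.09e-07). Comp (8:70373558-70382066), a cartilage matrix protein, was at 68.0 ± 19.7 against 988 ± 274 CPM (-3.86 ± 0.325, adjusted p = 4.18e-06).

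Il1f9 (2:24186476-24193568), an interleukin of the IL-36 group, was at 33.0 ± 3.22 against 0.738 ± 0.716 CPM (5.46 ± 0.523, adjusted p = 1.23e-05). Arg2 (12:79130777-79156301), the mitochondrial arginase, was at 51.0 ± 2.59 against 1.73 ± 0.850 CPM (4.87 ± 0.247, adjusted p = 1.18e-07). Retnlg (16:48872621-48874496), a resistin-like gene of neutrophils, was 5.24 ± 0.708 higher (adjusted p = 0.000184) and Stfa2l1 4.90 higher. Xist was at 78.1 ± 7.23 CPM against 3 counts in all, with a ratio interval of 526 to 7460 (adjusted p = 1.43e-07), and Tpm3-rs7 was 5.52 higher with the same uncertainty as above. Col2a1 (15:97975602-98004695), the collagen of cartilage, was at 1.52 ± 0.466 against 40.4 ± 9.34 CPM (-4.72 ± 0.414, adjusted p = 5.9e-06). Acan (7:79053483-79115099), the cartilage proteoglycan aggrecan, was at 3.87 ± 1.22 against 72.9 ± 27.5 CPM (-4.23 ± 0.408, adjusted p = 1.29e-05), and Matn4 (2:164389393-164405160), a matrilin, fell by 4.47. Cpxm2, Wscd2, C1qtnf3 and Adamts16 followed at -4.23, -4.19, -3.95 and -3.72. Il1f9 and Stfa2l1 were at 6.46 and 6.85 without WT CCR2hi replicate 1, and Retnlg at 4.57 without Bhlhe41Cre CCR2hi replicate 1.

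Of 24 inflammatory genes, 19 were higher and none lower (20 adjusted over the list alone), with Il1a (2.86) and Tnf (2.59) (camera 6.91e-20; adjusted p = 0.0573 with an estimated correlation). Lipid-associated genes, with Spp1 (3.23) and Lgals3 (2.30), had 16 of 22 higher by either count (camera 3.14e-11; adjusted p = 0.143 with an estimated correlation). Monocyte genes, with F10 (4.39), Clec4e (3.92, and 4.57 without WT CCR2hi replicate 1) and Chil3 (3.60), had 11 of 18 higher and 2 lower by either count (camera 3.93e-08; adjusted p = 0.0573 with an estimated correlation). Neutrophil genes, with S100a8, S100a9 and Csf3r (1.83), had 9 of 13 higher, 10 adjusted over the list alone (camera 2.51e-07; adjusted p = 0.198 with an estimated correlation). Macrophage identity genes, with Cd68 (1.98) and Cd14 (1.85), had 10 of 17 higher and 1 lower by either count (camera 1.59e-06; adjusted p = 0.387 with an estimated correlation). Alternative activation, with Il10 (3.46) higher and Egr2 (-1.30) lower, had 11 of 21 higher and 3 lower (11 and 4 adjusted over the list alone; camera 7.21e-05; adjusted p = 0.0573 with an estimated correlation). T and NK cell genes, with Il7r (2.04) and Lck (1.59), had 3 of 15 higher by either count (camera 0.0183; adjusted p = 0.628 with an estimated correlation, and 0.0618 after the GC and length correction, range 0.00924 to 0.628). Fibroblast genes, with Fbln1 (-1.30) and Mgp (-1.14), had 9 of 16 lower, 13 adjusted over the list alone (camera 0.000698; adjusted p = 0.643 with an estimated correlation). Under macrophage scaling the higher and lower calls were 10 and 1 for inflammatory, 8 and 4 for lipid-associated, 9 and 6 for monocyte, 8 and 1 for neutrophil, 4 and 4 for macrophage identity, 1 and 1 for T and NK cell and 0 and 16 for fibroblast genes. For alternative activation they were 4 and 6, with a median of 0.03.

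A further 7 lists were called higher, with medians that lie below 0 under macrophage scaling, as its move of -0.96 of the median gene gives. Glycolysis and hypoxia, with Slc16a3 (1.28) and Pkm (1.07), had 17 of 27 higher and 1 lower (20 and 2 adjusted over the list alone; median 0.63, turning to -0.39; camera 3.46e-06; adjusted p = 0.0578 with an estimated correlation). Oxidative phosphorylation, with Cox7a2 (0.88) and Uqcrfs1 (0.70), had 16 of 41 higher (18 adjusted over the list alone; median 0.36, turning to -0.68; camera 0.000149; adjusted p = 0.729 with an estimated correlation, and 0.424 after the GC and length correction, range 3.86e-06 to 0.729). Cell cycle, with Pcna (1.33) and Birc5 (1.03), had 11 of 33 higher by either count (median 0.50, turning to -0.65; camera 0.000386; adjusted p = 0.714 with an estimated correlation). Dendritic cell, with Cd24a (3.44), Xcr1 (3.26) and Ccr7 (2.91, and 4.02 without WT CCR2hi replicate 1), had 5 of 16 higher by either count (median 0.38, turning to -0.59; camera 0.0141; adjusted p = 0.16 with an estimated correlation). Matrix remodelling, with Mmp8 (3.93) and Adam8 (3.05) higher and Timp2 (-1.20) lower, had 11 of 24 higher and 7 lower (11 and 8 adjusted over the list alone; median 0.29, turning to -0.82; camera 0.0194; adjusted p = 0.3 with an estimated correlation). Type I interferon response, with Oasl1 (3.06) and Cxcl10 (1.91), had 7 of 27 higher and 2 lower by either count (median 0.21, turning to -0.75; camera 0.0403; adjusted p = 0.777 with an estimated correlation, range 0.0114 to 0.777, with 0.125 after the GC and length correction and 0.0527 with library size only). Cholesterol synthesis had 5 of 22 higher by either count (median 0.34, turning to -0.76; camera 0.0435; adjusted p = 0.544 with an estimated correlation). Cardiomyocyte genes were not called here, with 0 of 19 changed (0.802), and the other 11 lists not called had camera adjusted p from 0.051 to 0.654.

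Between genotypes 4808 genes (32.1%) differed in CCR2hi, 2424 higher and 2384 lower, of which 1869 changed by more than 2-fold. The share higher was 50.4% on the main scale, 35.1% with limma-trend on TPM (1663 and 3076), 61.8% with library size only (2994 and 1851) and 3.08% after macrophage scaling (305 and 9585). The genotype differences of the 2 gates correlated across genes at r = 0.481 (rho = 0.516). Calls of both gates shared 1004 genes higher, where independent calls give 397, and 1585 lower, where they give 636, and 155 were opposite. The libraries of the 2 gates may come from the same animals. Any batch, handling or sex difference that goes with genotype is in both gates, so this overlap does not replicate an effect of the genotype itself.

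The CCR2 status by genotype interaction asks whether the gates differ by another amount in Bhlhe41Cre than in WT. The cardiomyocyte, mural, neutrophil and monocyte lists had a lower CCR2low minus CCR2hi difference in Bhlhe41Cre with the preset correlation, and not with an estimated correlation (adjusted p = 0.0884, 0.0884, 0.186 and 0.0573). Fpr1 (17:17876471-17883940), a receptor for formyl peptides, went from 10.3 ± 1.61 in CCR2low and 1.13 ± 0.561 CPM in CCR2hi of WT to 10.2 ± 2.41 and 21.7 ± 7.02 CPM in Bhlhe41Cre (-4.26 ± 0.45, adjusted p = 0.000307). S100a9 went from 26.3 ± 14.3 and 14.8 ± 11.7 CPM in WT to 56.1 ± 8.99 and 434 ± 75.6 CPM in Bhlhe41Cre (-3.78 ± 0.701, adjusted p = 0.00637, and -4.46 without WT CCR2hi replicate 1). Tnnt2, cardiac troponin T, went from 25.1 ± 4.58 and 28.0 ± 2.99 CPM in WT to 7.27 ± 0.837 and 33.3 ± 2.22 CPM in Bhlhe41Cre (-2.04 ± 0.222, adjusted p = 0.000361). Matn4 went the other way, from 3.67 ± 1.88 and 74.8 ± 10.2 CPM in WT to 1.83 ± 0.114 and 3.37 ± 1.22 CPM in Bhlhe41Cre (3.47 ± 0.468, adjusted p = 0.00108).

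The largest positive term was that of Malat1 (19:5795690-5802672), a nuclear noncoding RNA that was high in WT CCR2hi replicate 2 (4.76 ± 0.929, adjusted p = 0.00896). It was 3.66 without that library and 5.36 without Bhlhe41Cre CCR2low replicate 3. Slc5a3 (16:92058322-92087473), the inositol transporter, had 3.53 ± 0.535 (adjusted p = 0.00205) and Nrg1 3.12 ± 0.462 (adjusted p = 0.00183). Lars2 (9:123366927-123462666), a mitochondrial tRNA synthetase, had 2.85 ± 0.804 (adjusted p = 0.0385, range 0.00758 to 0.126), a call that 12 of 24 alternatives ended, with a value of 1.38 without WT CCR2hi replicate 2. Among these were fits without any 1 of the WT CCR2low (0.0758, 0.0745 and 0.0749) or Bhlhe41Cre CCR2hi libraries (0.0686, 0.0608 and 0.069), and without Bhlhe41Cre CCR2low replicate 1 (0.0822) or 2 (0.101). The largest negative terms were those of Cyp2e1 (-9.41 ± 2.2, adjusted p = 0.0214), Marco (-4.92 ± 1.15, adjusted p = 0.0184), Itih4 (14:30886476-30902353), a plasma protein (-4.44 ± 0.844, adjusted p = 0.00704), and Alox15 (-4.27 ± 1.24, adjusted p = 0.042). The call of Cyp2e1 ended in 7 of 24 alternatives (range 2.7e-06 to 0.182), among them without WT CCR2hi replicate 1 (0.0713), Bhlhe41Cre CCR2low replicates 1 (0.0545) and 2 (0.057), and Bhlhe41Cre CCR2hi replicate 3 (0.073). That of Alox15 ended in 14 of 24 (range 0.00122 to 0.222), among them without any 1 of the WT CCR2hi (0.142, 0.073 and 0.0604), Bhlhe41Cre CCR2low (0.0843, 0.0977 and 0.0732) or Bhlhe41Cre CCR2hi libraries (0.0931, 0.121 and 0.111). The term of Marco ranged from 0.000527 to 0.107, with 0.107 under limma-voom, 0.069 without WT CCR2hi replicate 1, and 0.0659 and 0.0586 without Bhlhe41Cre CCR2hi replicates 2 and 3. Without WT CCR2low replicate 3 the terms of Cyp2e1, Marco, Itih4 and Alox15 were -6.2, -4.17, -3.29 and -3.04. Cyp2e1 had -8.76 without Bhlhe41Cre CCR2hi replicate 3, and Marco -4.14 and -5.6 without WT CCR2hi replicates 1 and 2 and -4.3 without Bhlhe41Cre CCR2hi replicate 2. Bhlhe40 had 0.76 ± 0.227 (adjusted p = 0.045, 2.11 with adjusted p = 0.0127 on the macrophage scale, range 0.00326 to 0.466). Its call ended without any 1 of the WT CCR2low libraries (0.0731, 0.107 and 0.0759) and without Bhlhe41Cre CCR2low replicate 1 (0.0779) or 2 (0.0863). Ccr2 had 1.05 ± 0.421 (adjusted p = 0.118), 1.5 (adjusted p = 0.0275) without WT CCR2hi replicate 1, and 2.16 (adjusted p = 0.00817) on the macrophage scale, which moved the median gene by 1.17.

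All 14 called lists had a lower term. Of 19 cardiomyocyte genes 17 were lower by either count, with Myh7 (-5.50), Ckmt2 (-2.91) and Mb (-2.49) (median -2.09; camera 2.99e-16; adjusted p = 0.0884 with an estimated correlation). Mural genes, with Myh11 (-2.47) and Acta2 (-1.85), had 7 of 10 lower, 9 adjusted over the list alone (median -1.63; camera 3.42e-09; adjusted p = 0.0884 with an estimated correlation). Neutrophil genes, with Lcn2 (-4.16, and -3.37 without Bhlhe41Cre CCR2hi replicate 1) and Csf3r (-2.15), had 8 of 13 lower, 12 adjusted over the list alone (median -3.54; camera 5.1e-08; adjusted p = 0.186 with an estimated correlation). Monocyte genes, with F10 (-3.06), had 9 of 18 lower and 1 higher (12 and 2 adjusted over the list alone; median -1.57; camera 1.37e-05; adjusted p = 0.0573 with an estimated correlation). T and NK cell genes, with Lck (-2.36), had 5 of 15 lower, 10 adjusted over the list alone (median -2.36; camera 2.69e-05; adjusted p = 0.3 with an estimated correlation). Resident cardiac macrophage genes, with Lyve1 (-3.39), Fcna (-3.29) and Ltc4s (-2.44), had 6 of 23 lower and 1 higher (8 and 3 adjusted over the list alone; median -1.18; camera 0.0033; adjusted p = 0.538 with an estimated correlation). Mast cell genes had 1 of 6 lower, 4 adjusted over the list alone (median -2.22; camera 0.0208; adjusted p = 0.235 with an estimated correlation). B cell genes, with Cd79a (-3.29), had 1 of 9 lower, 3 adjusted over the list alone (median -1.88; camera 0.0363; adjusted p = 0.606 with an estimated correlation, and 0.0823 with library size only, range 0.0206 to 0.606). Under macrophage scaling these medians stayed below 0, but the higher and lower calls were 0 and 7 for cardiomyocyte, 0 and 2 for neutrophil, 0 and 1 for T and NK cell, 3 and 3 for monocyte, 5 and 4 for resident cardiac macrophage (median -0.05), and 0 and 0 for mural, mast cell and B cell genes.

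The other 6 called lists had medians that lie above 0 under macrophage scaling, as its move of 1.17 of the median gene gives. Inflammatory genes, with Il1a (-2.11), Il1b (-1.91) and Tnf (-1.73), had 11 of 24 lower, 13 adjusted over the list alone (median -1.20, turning to 0.01; camera 5.84e-08; adjusted p = 0.16 with an estimated correlation). Macrophage identity genes, with Cd14 (-1.87) and Itgam (-1.50), had 7 of 17 lower, 11 adjusted over the list alone (median -1.01, turning to 0.04; camera 1.81e-07; adjusted p = 0.359 with an estimated correlation). Alternative activation, with Il10 (-1.88) and Clec7a (-1.45), had 8 of 21 lower, 9 adjusted over the list alone (median -0.98, turning to 0.12; camera 5.87e-05; adjusted p = 0.0573 with an estimated correlation). Lipid-associated genes, with Gpnmb (-3.05) and Lgals3 (-2.08), had 9 of 22 lower (13 lower and 1 higher adjusted over the list alone; median -0.89, turning to 0.34; camera 7.01e-05; adjusted p = 0.31 with an estimated correlation). Oxidative phosphorylation had 1 of 41 lower by either count (median -0.37, turning to 0.86; camera 0.0148; adjusted p = 0.829 with an estimated correlation), and after the GC and length correction its direction turned (adjusted p = 0.926, range 0.000744 to 0.926). Endothelial genes had 2 of 13 lower, 3 adjusted over the list alone (median -0.67, turning to 0.50; camera 0.0155; adjusted p = 0.726 with an estimated correlation). Fibroblast genes had 1 of 16 lower, 0 adjusted over the list alone (median -0.30; 0.705), and the other 12 lists not called had camera adjusted p from 0.0696 to 0.945. Cell cycle and type I interferon medians had the opposite sign to the test.

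The interaction was called for 1884 genes (12.6%), 710 higher and 1174 lower, of which 1366 were past 2-fold. Without Bhlhe41Cre CCR2low replicate 1 the count was 871, without Bhlhe41Cre CCR2hi replicate 3 it was 927, without WT CCR2low replicate 2 it was 953, without WT CCR2low replicate 1 it was 1138, and with limma-trend on TPM it was 1080. The share higher was 37.7% on the main scale, 19.5% with library size only (447 and 1844), 19.7% after the GC and length correction (373 and 1525), 47.8% with RLE (831 and 908), 62.5% with no filter, 66.3% with a filter of 5 CPM, 97.7% after macrophage scaling (5617 and 131) and 49.9% without the 2 WT libraries doubted for fat cell genes and ribosomal RNA (851 and 854).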

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

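Of the tests in this part, the 9 on fibroblast genes, on the genotype difference in CCR2low and on kidney genes were chosen only after the results were seen, while the counts over other splits of the libraries were planned. By the planned rule a share under 0.05 spoke against chance for the interaction, and that rule was set aside after its result was seen. The reading of the fibroblast count was also changed after it was seen, and the count on heart cells in the kidney part replaced an earlier one, that Kap had 0 counts in the other 9 libraries. The results below stand here because the difference between the gates differed between the genotypes by the interaction term, which was tested with edgeR for single genes and with camera for lists.

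The interaction was called for 1884 of 14964 genes. Among 100 drawn splits of the libraries, the real one included, 3 gave as many calls, and the highest of the others gave 7674. The 85 splits that mix the genotypes in both gates gave 0 calls, since the genotype differences enter their spread, so the share says nothing on chance for the interaction. The split with 7674 calls kept the WT libraries together in CCR2low and exchanged the genotypes in CCR2hi, so it tests the sum of both genotype differences and points to a structure of the samples. The second highest gave 3152. For the gate and genotype comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real split was the only 1 of 10 with as many calls in CCR2low vs CCR2hi in WT (8949, highest other 0), CCR2low vs CCR2hi in Bhlhe41Cre (8094, highest other 0), Bhlhe41Cre vs WT in CCR2low (6441, highest other 0) and Bhlhe41Cre vs WT in CCR2hi (4808, highest other 1). In Bhlhe41Cre, residuals matched the gates best by number for replicates 1 and 3 but not 2. There, 4 of the 10 splits part all 3 same-number pairs, and the 3 of these that are not the real one gave 0 calls. The other 6 splits leave 1 pair whole on each side.

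Single genes with an interaction were Malat1 at 4.76, Slc5a3 at 3.53, Matn4 at 3.47, Nrg1 at 3.12, Lars2 at 2.85, Bhlhe41 at 1.46 and Bhlhe40 at 0.76. On the negative side they were Cyp2e1 at -9.41, Marco at -4.92, Itih4 at -4.44, Alox15 at -4.27 and Fpr1 at -4.26. Malat1 had 10950 counts in WT CCR2hi replicate 2, against 2854 and 2312 in the other libraries of its group, and without it the terms of Malat1 and Lars2 were 3.66 and 1.38. Without WT CCR2low replicate 3 those of Cyp2e1, Marco, Itih4 and Alox15 were -6.2, -4.17, -3.29 and -3.04. With other libraries left out, Malat1 reached 5.36 (Bhlhe41Cre CCR2low replicate 3), Cyp2e1 -8.76 (Bhlhe41Cre CCR2hi replicate 3) and Marco -4.14, -5.6 and -4.3 (WT CCR2hi replicates 1 and 2, Bhlhe41Cre CCR2hi replicate 2). Lists with an interaction had medians of -3.54 (neutrophil), -2.36 (T and NK cell), -2.22 (mast cell), -2.09 (cardiomyocyte), -1.88 (B cell), -1.63 (mural), -1.57 (monocyte) and -1.18 (resident cardiac macrophage). Under macrophage scaling these stayed below 0, but resident genes had 5 higher and 4 lower calls, monocyte genes 3 and 3, and mast cell, B cell and mural genes none. Those of -1.2 (inflammatory cytokines and chemokines), -1.01 (macrophage identity), -0.98 (alternative activation), -0.89 (lipid-associated macrophage), -0.67 (endothelial) and -0.37 (oxidative phosphorylation) lie above 0 under that scaling, as its move of 1.17 of the median gene gives. None of these 14 list calls held with an estimated correlation, with adjusted p of 0.0573 or more.

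Fibroblast genes were higher in the CCR2hi libraries of both genotypes, with Col1a1 at 19090 ± 2788 CPM in WT CCR2hi and 8164 ± 745 CPM in Bhlhe41Cre CCR2hi. A lower macrophage share alone raises all other cell types alike, whereas in WT the fibroblast median rose 1.78 more than the endothelial one, with 1.36 between the nearest quartiles of the lists. GC content or gene length is argued against as the whole cause, since the fibroblast median stayed at -3.22 (quartiles -3.43 and -2.99) after the correction, with all 16 genes called. RNA of fibroblasts in the CCR2hi libraries and transcription of these genes by the sorted CCR2hi cells cannot be told apart, because the 16 of 16 genes called higher in both genotypes restate the pattern and either would give them. A sort for macrophage surface markers would remove fibroblasts, but how far it did so here was not tested. Macrophage identity genes took 0.415 ± 0.161% of counts in WT CCR2hi against 3.46 ± 0.152% in WT CCR2low. In WT CCR2hi, 12 of 13 endothelial and 9 of 10 mural genes were higher too and 0 lower, while the cardiomyocyte list was not called.

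The genotypes differed in CCR2low at 6441 genes, while fold changes followed GC content and the Bhlhe41Cre libraries held Xist. GC content or gene length could not be the whole cause, since 73.5% of the calls (4733) kept call and direction after the correction. Sex-linked genes of female RNA could not be either, since 3.04% of the calls lay on X or Y against 3.23% of the genes tested. Autosomal genes that differ by sex remain open, since every Bhlhe41Cre library held Xist and none of the WT libraries had more than 3 counts of it. Sample handling that goes with genotype and an effect of the genotype itself cannot be told apart, because 13 of 24 immediate early genes were lower in Bhlhe41Cre in both gates and all libraries of a genotype may have been handled together.

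Genes of the kidney tubule were counted in all 3 WT CCR2low libraries, with Kap at 507, 487 and 413, Umod at 89, 105 and 70, and Slc34a1 at 82, 84 and 76 counts. Kidney RNA and heart cells that every group holds, in a larger share here, cannot be told apart, because the other 9 libraries held 11.8% (median, quartiles 0.538 and 62.8) of the mean count here for 16 further kidney genes, and 33.5% (19.8 and 47.8) for mesothelial genes. Kidney RNA or reads in these libraries remain a candidate source. Of the 16 further kidney genes, 9 had all 3 WT CCR2low libraries above the other 9. Libraries without group differences would give 0.073, but these groups differed at many genes. Mesothelial genes such as Msln and Upk3b, though not Wt1, met this criterion too, so the count cannot decide between sources. Of the 24 listed genes, 13 had at least 10 counts in each of these 3 libraries and at most 10 in every other, against 0 of 15 mesothelial genes, and 4 had at least 10 in every other library. Transcription by WT CCR2low macrophages cannot be told apart from RNA spread evenly over the 3 libraries, because the summed counts of 8 leading genes ran from 881 to 1064, a ratio of 1.21, which either would give.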

How the results depend on the processing

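The GC and length correction, macrophage scaling, the 2 WT libraries left out together and the autosomal genes were chosen only after the data were seen. In every alternative to the 5 counts of called genes other than those below, counts stayed within 1.5 times the main value. Against a 1.5-fold minimum the counts were 5509, 4928, 2486, 1329 and 478 (in the order of the report), fewer by construction. Macrophage scaling gave 14317, 13604, 2407, 9890 and 5748, with 4613, 4443, 2402, 2689 and 836 main calls kept in direction. Of the 527 calls of named genes on the main scale, macrophage scaling kept 336 in the same direction, and the others were lost or turned. The interaction had 1080 calls with limma-trend on TPM and 871 to 2801 with 1 library left out. These were 871 and 927 without Bhlhe41Cre CCR2low replicate 1 and CCR2hi replicate 3, 1138 and 953 without WT CCR2low replicates 1 and 2, and 2801 without Bhlhe41Cre CCR2low replicate 3. The cause was not tested. Without WT CCR2low replicate 3 and WT CCR2hi replicate 2 the counts were 8167, 8078, 5824, 3446 and 1705, on autosomes 8628, 7794, 6242, 4639 and 1823, and with replicate blocks 9052, 8244, 5327, 3636 and 2156. With an estimated correlation 0 of 60 list calls held (lowest adjusted p 0.0573), while blocks, library size, the GC and length correction, and macrophage scaling kept 60, 58, 54 and 54. The list oxidative phosphorylation reversed in the interaction after that correction (0.926), and the cause was not tested. The correlation of gate differences was 0.845 for genes with a mean of at least 5 CPM, 0.777 after the correction (the cause was not tested) and 0.682 to 0.741 with 1 library left out. That of genotype differences was 0.573 for genes of at least 5 CPM and 0.421 to 0.482 with 1 library left out. The filter on the mean took in fewer genes, which moves these correlations by construction. Fits without a library tested more genes with low counts, and how far this or the lost library moved the correlations was not tested. Named genes reversed in none of the alternatives other than macrophage scaling, and 485 to 513 of 527 were called with 1 library left out. Depth limited folds for genes with 3 or fewer counts in a group, such as Kap and Xist, to bounds or counting intervals.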

Other observations

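Tests of values relative to the macrophage identity genes were chosen only after the data were seen, as was every list of kidney, fat cell and mesothelial genes. Some clock genes differed by gate and by genotype. In CCR2low vs CCR2hi in WT, Npas2 (-3.08), Rora (-2.26), Arntl (-2.02) and Clock (-1.37), which carry or drive the positive arm of the clock, were lower in CCR2low, while the clock list had 6 genes higher and 6 lower of 19 (camera adjusted p = 0.643). In Bhlhe41Cre vs WT in CCR2low, Per2 (-1.54), Per1 (-1.51) and Nfil3 (-1.1) were lower and Clock (1.52) higher. Macrophage scaling, a move of 0.2, could not turn these. Fold changes followed GC there. The clock list there had 10 of 19 lower and 5 higher (camera adjusted p = 0.342). The list was called in no comparison.

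Gdf15 (3.82) and Osm (3.03), cytokines made by stressed or activated myeloid cells, were higher in CCR2low of WT, while Tgfb3 (-2.82) was lower. On the macrophage scale these were 0.68, -0.1 and -5.96, so Osm did not differ there (adjusted p = 0.702). Gdf15 and Osm had interaction terms of -1.88 and -2.03, against -0.71 (adjusted p = 0.145) and -0.86 (adjusted p = 0.0556) on the macrophage scale. The growth factor list was not called in any comparison, with 13 genes higher and 8 lower of 26 in CCR2low of WT (camera adjusted p = 0.36). Of 14 genes of MHC class II antigen presentation, 2 were higher and 1 lower in CCR2low of WT (camera adjusted p = 0.903). On the macrophage scale none was higher and 14 were lower, as were 14199 of all 14964 genes there, so that count does not set the list apart. H2-Eb1 was -0.99 (adjusted p = 0.0185) and H2-Ab1 -0.77 (adjusted p = 0.0625) in WT.

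Some genes of the mesothelium, the lining of the heart and of body cavities, had their highest counts in WT CCR2low. Msln had 1024, 1230 and 968 counts there and Upk3b had 1210, 1173 and 764, while Wt1 had 153, 203 and 176 against 386, 467 and 526 in WT CCR2hi. Of the 15 mesothelial genes listed, 12 had at least 10 counts in every other library. Among fat cell genes, Cfd had 12046 counts in WT CCR2low replicate 3 against 265 and 508 in the other libraries of the group, and Adipoq had 1679 against 57 and 144. Ribosomal RNA took 1.74% of counts in WT CCR2hi replicate 2 and at most 0.344% in the other 11 libraries. The mitochondrially encoded genes took 6.87 ± 1.19% of counts in WT CCR2hi, 2.88 ± 0.743% in WT CCR2low, 2.81 ± 0.574% in Bhlhe41Cre CCR2hi and 1.72 ± 0.185% in Bhlhe41Cre CCR2low. Rpl15-ps2, a processed pseudogene whose reads cannot be assigned with certainty, had at most 2 counts in every WT library and 96 to 321 in the Bhlhe41Cre libraries.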
